A study of Mus musculus with 4 samples.

How the data were processed

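The values analysed were those of 4 arrays, 1 for each of 4 groups of mice: control diet, diet with 0.2% cholic acid (CA), diethylnitrosamine (DEN) with control diet, and DEN with CA diet. Per the labels, each array was hybridised with RNA of pooled livers of 3 to 5 mice at 10 months of age. Total RNA was isolated with Trizol, and 1 µg was labelled with a biotin dendrimer kit (FlashTag Biotin HSR), per the labels' protocols. This kit is known from microRNA arrays, and how it was used for this array is not given in the sources used here. The array was an Affymetrix mouse expression array with 45101 probe sets, of which 64 are control probe sets. The deposited values are log2 expression values made by the authors with RMA in Partek 6.5, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a probe set; the options used are not given in the sources used here. The values ran between medians of 4.843 and 4.865 on the 4 arrays, with no detection call. Because the method draws the distributions together, a change of most genes in the same direction would be removed.

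Probe sets were named through the platform annotation supplied with the values, which listed 35890 of them. Of these 34958 had 1 gene symbol and 932 several, and 9211 others had no name here. Symbols were checked through gene identifiers against the RefSeq mouse annotation of GRCm38.p6, which matched 34754 probe sets and changed 0 symbols. No coordinates were used. A gene took the value of its probe set with the highest mean over the 4 arrays among those with 1 symbol, which gave 18194 genes, 9012 of them with several probe sets. Genes with a mean of at least 4.855, the median over all probe sets, were called expressed (11651). A gene was counted as different from 2-fold on, which is a log2 difference of 1.

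5 comparisons of 2 arrays and the difference between both diet effects were computed as values. With 1 array per group no test and no p-value was made. The groups, comparisons, gene lists, rule for named genes and alternatives were fixed before the data were examined. The 26 gene lists covered bile acid synthesis, bile acid receptors and transport, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipid droplets, glucose metabolism, hepatocyte identity, phase I drug metabolism, NRF2 targets, p53 targets, ER stress, cell cycle, tumour markers, WNT and pericentral genes, periportal genes, acute phase proteins, inflammatory genes, interferon response, matrix, circadian clock, male-biased, female-biased and sex chromosome genes, oxidative phosphorylation and ribosomal proteins. The 12 marker lists covered cholangiocytes, stellate cells and fibroblasts, macrophages, dendritic cells and MHC class II, T and NK cells, B and plasma cells, neutrophils, endothelial cells, erythroid cells, adipocytes, exocrine pancreas, and gallbladder and intestinal epithelium. Members that no probe set with 1 symbol names are not analysed here. A list is described by its median log2 difference over expressed members and by the percentile of that median among 10000 random lists of the same size, drawn from expressed genes in 20 bins of mean expression. The percentile describes these arrays and is not a p-value. The text names, for each comparison, genes from the 8 with the largest difference each way (6 for the difference between the diet effects, predicted genes left out). It also names up to 4 members of each list with the largest differences, and a set of liver, tumour and inflammation genes named in advance. A fold against a level under 4.855 was computed with that level raised to 4.855. This form of the fold was chosen after the data were seen.

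Alternatives were no expression filter, a filter at the upper quartile, a 1.5-fold threshold, quantile normalization, centring each array on its median over expressed genes, loess centring (fraction 0.3), the mean over probe sets, every probe set counted alone, and values below 4.855 raised to it. For lists, all measured members, the mean and unmatched random lists were also tried, and for the agreement of effects Spearman correlation and all genes. The steps were tested on simulated data made from the probe set means with normal noise (SD 0.14 per array), with known changes on the CA diet without DEN. In the CA diet comparison without DEN, over 11684 genes, all 50 genes changed 4-fold upwards and all 50 changed 3-fold upwards passed 2-fold. Of 50 genes changed 4-fold downwards 41 stayed expressed, and these 41 passed. Of 50 genes changed 1.5-fold 1 passed, and 0 of 11493 unchanged genes did. For the simulated DEN comparison on the control diet, without any change, 1 of 37 lists fell outside the central 95%. The noise was independent for each probe set, so this does not show how lists of genes that vary together behave. Its SD came from the CA diet comparison without DEN, whose spread over genes was 0.193, against 0.331 for DEN on the control diet. At that SD unchanged genes could hardly reach 2-fold, so the simulation checks the steps and not the rate of false calls between real pools. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.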

Results

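Hepatic gene expression was measured in mice at 10 months of age in a design that crossed 2 treatments. The treatments were diethylnitrosamine (DEN), a chemical that initiates liver tumours in mice, and a diet with 0.2% cholic acid (CA), a primary bile acid. The 4 groups were control diet, CA diet, DEN with control diet and DEN with CA diet, and each was measured on 1 array. Each array held RNA pooled from the livers of 3 to 5 mice, so there was no replicate, no test of a difference was made, and mouse-to-mouse variation could not be separated from the treatments. Every difference below is that of 2 pools, and the number of arrays limits its precision. The series title speaks of tumours while the sample labels name livers. How much tumour tissue each pool held is not given in the sources used here.

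The 4 arrays had medians between 4.843 and 4.865 over all probe sets on the log2 scale. Of 18194 named genes, 11651 were expressed, with a mean over the arrays of at least 4.855. Lower levels lie close to the background of the array, so that a fold against such a level was computed with the level raised to 4.855 and is given as "at least". Over expressed genes the arrays correlated at 0.987 between the diets without DEN and at 0.990 between the diets after DEN. The correlation was 0.953 between DEN and no DEN on the control diet and 0.949 on the CA diet. These correlations run across genes, which are not independent replicates. As a technical reference, the 18 probe sets for hybridization controls differed by at most 0.305, 0.203, 0.267, 0.370 and 0.184 in the 5 comparisons of 2 arrays, in the order in which these are described here. Poly-A control RNAs, which are usually added before labelling, differed more, with median differences from -0.35 to 0.45 over 24 probe sets.

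**Figure D1:**
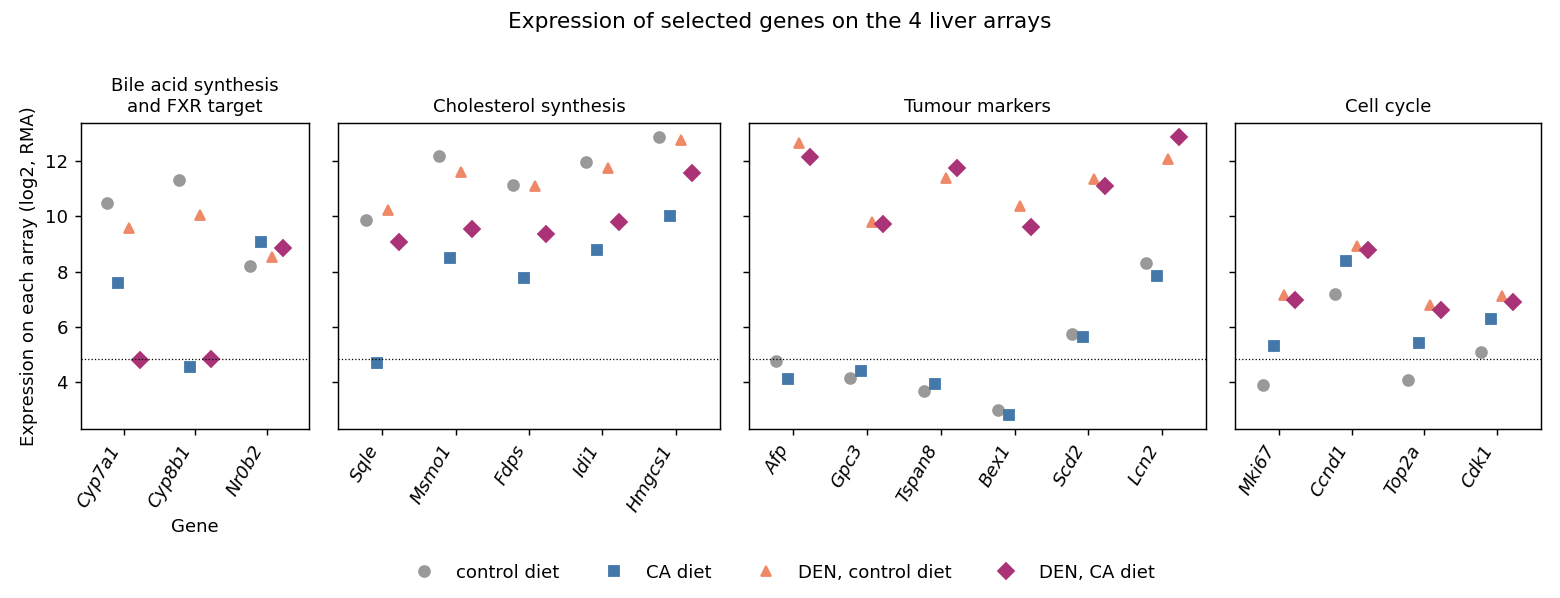
Expression (log2, RMA) of genes of bile acid synthesis, cholesterol synthesis, liver tumours and the cell cycle on each of the 4 arrays, 1 symbol per array; the dotted line marks 4.855, the median over all probe sets. Cyp8b1 lies at 11.32 and 10.07 on the control diet and at 4.55 and 4.85 on the CA diet, and Afp lies at 4.77 and 4.10 without DEN and at 12.65 and 12.17 after DEN.

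The CA diet against the control diet in mice without DEN addresses what a bile acid load alone goes with. Of the 8 most strongly lower named genes, all but Moxd1 belonged to bile acid or cholesterol synthesis. Cyp8b1, the sterol hydroxylase that directs bile acid synthesis towards cholic acid, was at least 88.2-fold lower (log2 level 11.32 on the control diet and 4.55 on the CA diet). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 7.54-fold lower. Sqle, the squalene epoxidase of cholesterol synthesis, was at least 32.4-fold lower, and Msmo1, Fdps, Idi1 and Hmgcs1, enzymes of the same pathway, were 12.7-fold, 10.3-fold, 9.05-fold and 7.36-fold lower. The other probe set of Fdps differed by only -0.22. In all, 77 genes were at least 2-fold higher and 69 at least 2-fold lower.

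Of the 19 expressed genes of cholesterol synthesis and uptake, 14 were at least 2-fold lower on the CA diet and none was higher by that much (median log2 difference -1.99). Among the 16 genes of bile acid synthesis and conjugation only Cyp7a1 and Cyp8b1 were lower by 2-fold or more (median -0.15). Cyp7b1, of the alternative pathway, differed by -0.44 and the mouse bile acid hydroxylase Cyp2c70 by 0.49. The receptors, FXR targets and transporters had a median of 0.17. Nr0b2, the repressor induced by the bile acid receptor FXR, was 1.83-fold higher (8.22 and 9.09), Slc51b, an exporter of bile acids, was 1.63-fold higher, and the sterol exporter gene Abcg5 was 2.70-fold higher. Abcb11, the bile salt export pump, differed by 0.25, the bile acid importer Slc10a1 by -0.38 and the FXR gene Nr1h4 by -0.25. Abcb1a, a drug efflux pump, was at least 3.54-fold higher. Genes of fatty acid synthesis had a median of -0.27, with Acss2 (-1.78), Elovl5 (-1.26), Acacb (-1.21) and Me1 (-1.03) lowest. Genes of lipid droplets had a median of -0.21, and Pparg, a regulator of lipid storage, was 2.13-fold lower. Moxd1, a monooxygenase relative, was at least 17.1-fold lower, and Asns, the asparagine synthetase gene of the amino acid stress response, was at least 5.33-fold lower.

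Higher genes on the CA diet without DEN included immediate early genes and cytochromes. Fos was 14.2-fold higher and Jun 3.25-fold higher, Egr1 3.19-fold and Socs3, a feedback inhibitor of cytokine signals, 2.75-fold. Cyp2b9 and Cyp2b13, drug-metabolising cytochromes, were 5.03-fold and at least 3.09-fold higher; they are close in sequence and the array does not separate them with certainty. Obp2a, an odorant-binding protein gene, was 4.55-fold higher, and the kinase gene Wnk4 was at least 1.95-fold higher. Hsd17b6, a steroid dehydrogenase gene, was 3.79-fold higher on the probe set used, while its other probe set differed by 0.05. Of 28 expressed cell cycle genes, 10 were at least 2-fold higher and none lower by that much (median 0.70), with Ube2c at 1.53, the proliferation marker Mki67 at 1.42, Ccne2 at 1.39 and Top2a at 1.35. Several of these were close to background on the control diet (Mki67 3.90, Top2a 4.06), and with low values raised to 4.855 the median of the list was 0.30 and Mki67 stood at 0.46, while another probe set of Top2a differed by -0.38. Ccnd1, the cyclin of entry into the cycle, was 2.28-fold higher (7.20 and 8.38). Inflammatory cytokines and NF-kB targets had a median of 0.24 with 5 of 22 at least 2-fold higher. Among these were Egr1 and Socs3, already named above, and the chemokine genes Cxcl10 (1.67) and Cxcl1 (1.27). The interferon response had a median of 0.38, with Ifi27l2a at 1.19 and Usp18 at 1.04. Markers of Kupffer cells and macrophages stood at a median of 0.54, with Marco at 1.30 and Cd5l at 0.78, beside these inflammatory groups. Dendritic cell and MHC class II markers stood at 0.34 and cholangiocyte markers at 0.30. The 3 expressed neutrophil markers stood at 0.63, but all 10 measured ones at 0.00936.

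For the diets without DEN, 16 of 37 lists with at least 3 expressed members had medians above the central 95% of random lists. Another 5 had medians below it. Lists of unrelated genes would put 1.85 outside. Genes of a list can vary together and some lists share members, so 1.85 is not the number to expect between 2 like pools. This describes the 2 arrays and is not a test between diets.

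DEN against no DEN on the control diet addresses what the carcinogen alone goes with in livers at 10 months of age. Oncofetal and tumour genes were among the genes with the largest differences. Afp, alpha-fetoprotein, was at least 222-fold higher (4.77 and 12.65), and Gpc3, the oncofetal glypican, at least 30.9-fold higher (4.14 and 9.80). The tetraspanin gene Tspan8 was at least 92.0-fold higher, Cpe, carboxypeptidase E, at least 73.6-fold, Bex1 at least 45.7-fold, and Scd2, a fatty acid desaturase, 49.9-fold. Other probe sets of Afp and Cpe did not show this, with the lowest at 0.19 and -0.51, and the lowest of Tspan8 and Scd2 stood at 0.88 and 0.73. In all, 596 genes were at least 2-fold higher and 105 lower, and with each array centred on its median over expressed genes these were 455 and 192. The median difference over expressed genes was 0.035 before this centring, which shifted it by -0.16 and so moved it away from 0. Loess centring gave 567 and 108, and quantile normalization 526 and 121.

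Of 25 expressed oncofetal and tumour markers, 18 were at least 2-fold higher and none was lower by that much (median 2.30). Beyond those named, Tff3, a secreted trefoil peptide, was 41.2-fold higher, Prom1 at least 28.9-fold, Spink1, a trypsin inhibitor, at least 19.3-fold, and Lcn2, lipocalin 2, 13.4-fold (8.32 and 12.06). Klrb1b, a lectin-like receptor gene of natural killer cells, was at least 13.5-fold higher. Cell cycle genes were higher together, 18 of 28 by at least 2-fold and none lower by that much (median 1.5804), led by Mki67, Ube2c, Top2a and Ccnb2. These 4 were under 4.855 on the control diet, and with low values raised to it they stood at 2.30, 2.57, 1.93 and 1.46 and the list at 1.15. Ccnd1 was 3.29-fold higher and Myc 1.52-fold higher. Of 17 expressed p53 targets 8 were at least 2-fold higher (median 0.71, or 0.30 with the mean over the probe sets of each gene), led by the antiproliferative gene Btg2 (3.04) and the cell cycle inhibitor Cdkn1a (2.54). Targets of NRF2, the regulator of the oxidative stress response, had a median of 0.41 (0.25 with each array centred on its median), with Cbr3 at 3.95, Gstm3 at 2.23, Srxn1 at 1.93 (its lowest probe set at 0.03) and Osgin1 at 1.54. Genes of the ER stress and amino acid response had a median of 0.49, with Asns at 1.80 and Trib3 at 1.65. Igfbp1, an insulin-regulated binding protein, was 14.5-fold higher.

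The matrix, inflammatory and interferon lists also had medians above 0 in the DEN pool. Of 17 expressed matrix genes 9 were at least 2-fold higher (median 1.03), with Col5a2 at 2.86, Col3a1 at 1.94 and Col4a1 at 1.89. Col1a1 was low on every array (4.55 to 5.59). Inflammatory genes had a median of 0.59 with 8 of 22 at least 2-fold higher, among them Egr1 (3.45), Cxcl9 (2.98), Ccl5 (2.36) and Cxcl10 (2.20), while Il1b differed by 0.15 and Stat3 by 0.16. Tnf and Il6 lay under the expression limit. Interferon response genes had a median of 0.78, with Oas1a at 1.66. Alongside them, marker lists of other cell types were higher to different degrees. The medians were 1.59 for cholangiocytes, 1.46 for dendritic cells and MHC class II, 0.67 for macrophages, 0.67 for B and plasma cells, 0.43 for stellate cells and fibroblasts and 0.31 for endothelial cells. These cover expressed members only. Over all measured members the medians were 0.78 for cholangiocytes (12 genes), 0.31 for dendritic cells and MHC class II (10) and 0.26 for B and plasma cells (10). With each array centred on its median, stellate and endothelial markers stood at 0.27 and 0.15. Among 3 neutrophil markers S100a8 and S100a9 were at 2.48 and 1.78 from levels under 4.855, while the receptor gene Csf3r was at 0.07 and all 10 measured neutrophil markers had a median of -0.09. The 4 expressed T and NK cell markers had a median of -0.09. Examples were the antigen presentation gene H2-Ab1 (2.06), the macrophage gene Mpeg1 (1.89), the monocyte receptor gene Cd14 (3.04) and the smooth muscle actin gene Acta2 (1.94, its lowest probe set 0.06). The cholangiocyte list shares Tspan8, Sox9 and Epcam with the tumour list.

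Lower genes in the DEN pool included acute phase genes, clock-driven genes and transporters. Saa2 and Saa1, serum amyloid A proteins of near-identical sequence, were 8.25-fold and 6.53-fold lower, and Orm2, orosomucoid 2, was 6.07-fold lower, although the acute phase list as a whole had a median of 0.08. Dbp, a transcription factor driven by the circadian clock, was 6.44-fold lower, and Usp2 and Upp2, a ubiquitin protease and a uridine phosphorylase gene, were 5.29-fold and 4.75-fold lower. The clock list had a median of -0.64, with Arntl 5.43-fold higher (its other probe set at -0.20) and Per3 2.60-fold lower. The drug-inducible cytochrome Cyp2b10 was 4.00-fold lower, and the matrix peptide gene Cnmd 3.85-fold lower. The uptake transporters Slco1a1 and Slco1b2 were 2.94-fold and 2.72-fold lower. Bile acid synthesis had a median of -0.50, with Cyp8b1 at -1.25, Akr1d1 at -1.21, Cyp7b1 at -1.05 and Cyp7a1 at -0.92. Genes of cholesterol synthesis were near 0 (median -0.04, none 2-fold different). Hepatocyte identity genes were also close to 0 (median -0.12), with Hnf4a at -0.12.

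For DEN on the control diet, 17 lists stood above the central 95% of random lists and 8 below it.

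**Figure D2:**
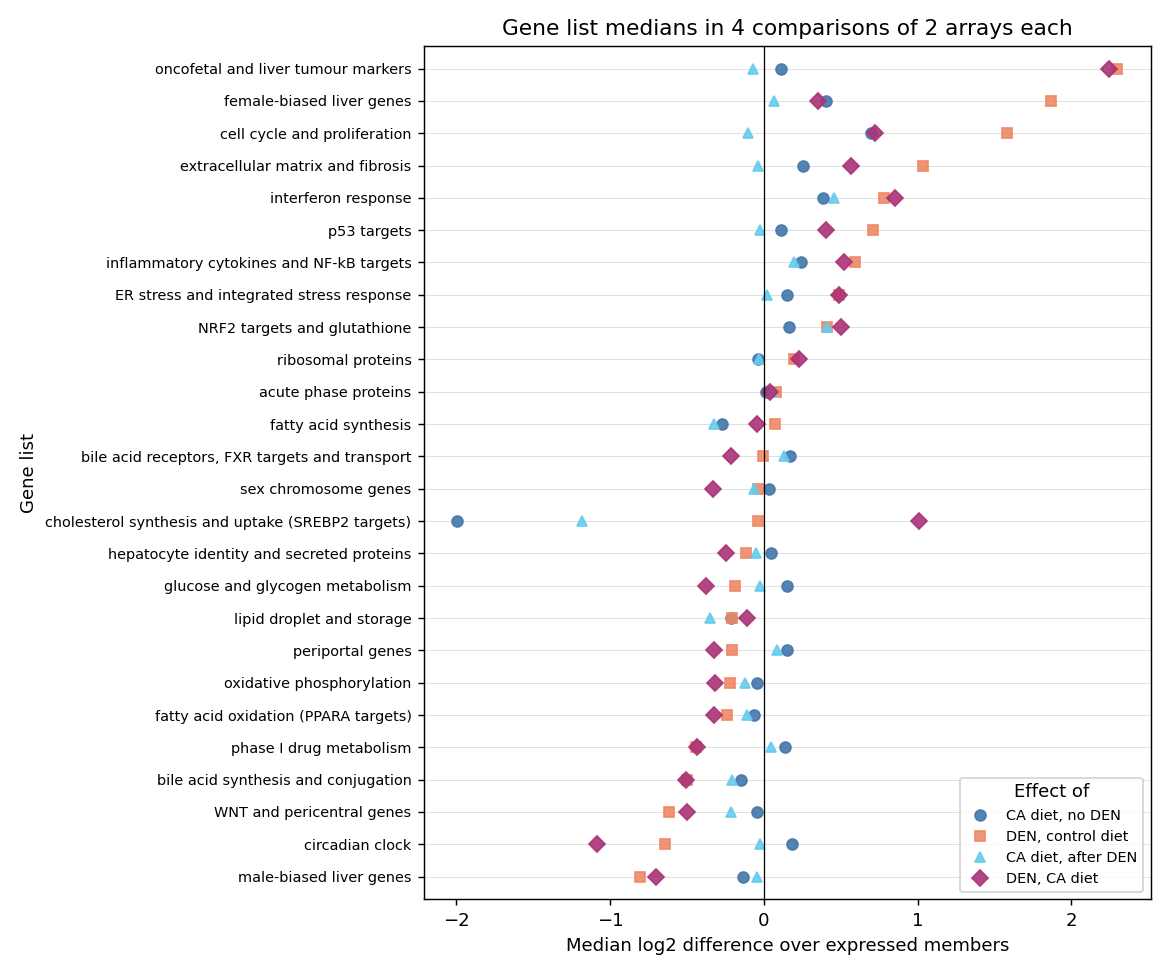
Median log2 difference over the expressed members of each of the 26 gene lists in 4 comparisons of 2 arrays; each symbol is 1 comparison and the vertical line marks no difference. Tumour markers lie at 2.30 and 2.24 for DEN on the 2 diets, and cholesterol synthesis at -1.99 and -1.18 for the CA diet without and after DEN.

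The CA diet against the control diet after DEN is the comparison named by the series title, promotion by a bile acid in mice given the carcinogen. Cyp8b1 and Cyp7a1 were the most strongly lower genes. Cyp8b1 was at least 37.0-fold lower (10.07 and 4.85) and Cyp7a1 at least 26.4-fold lower (9.58 and 4.80). Cholesterol synthesis was lower as a group, with Msmo1 4.08-fold, Idi1 3.86-fold, Fdps 3.40-fold and Fdft1 3.26-fold lower. Oncofetal markers were about as high on both diets, with Afp at -0.48, Gpc3 at -0.07 and a list median of -0.07, although Tff3 was 2.40-fold lower. In all, 31 genes were at least 2-fold higher and 55 lower.

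Of 19 expressed cholesterol genes, 12 were at least 2-fold lower (median -1.18), and these 12 were also at least 2-fold lower without DEN. FXR targets and transporters had a median of 0.13, with Slc51b at 0.93, Abcg5 at 0.80, Abcg8 at 0.70, Nr0b2 at 0.34, Abcb11 at 0.27, Slc10a1 at -0.51 and Slco1a4 at -1.07. Fatty acid synthesis had a median of -0.32, with Thrsp, a lipogenic nuclear protein, 2.74-fold lower and Acss2 2.63-fold lower. The lipid droplet list had a median of -0.35, with Lpin1, a phosphatidate phosphatase, 2.10-fold lower. Ppp1r3g, a subunit that directs a phosphatase to glycogen, was at least 2.58-fold lower. Noct, a rhythmic gene encoding nocturnin, was 3.71-fold lower, the nicotinamide methyltransferase gene Nnmt 3.61-fold, Upp2 3.52-fold and the aminotransferase gene Tat 2.36-fold.

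Higher genes on the CA diet after DEN were fewer. Obp2a was at least 7.79-fold higher and Csn3, kappa-casein, 3.99-fold higher (8.27 and 10.27). Rad51b, a recombination gene, was 4.32-fold higher on the probe set used while another probe set differed by -0.38. Vil1, villin of brush borders, was 3.23-fold higher, Ltb, lymphotoxin beta, 3.06-fold, Anxa13, an epithelial annexin, 2.87-fold, the protease inhibitor gene Wfdc12 2.70-fold and Socs2, a regulator of growth hormone signals, 2.57-fold. Among genes named for this comparison, other probe sets lay near 0 or on the other side for Fdps (0.12), Fdft1 (0.02), Thrsp (0.16), Upp2 (-0.14) and Socs2 (-0.10). Fos was 2.14-fold higher. Lcn2 differed by 0.83, Saa1 by 0.93, Il1b by 0.73 and Cdkn1a by 0.13. Cell cycle genes had a median of -0.11, with Cdkn3 at -1.03, Aurka at -0.48, Mcm6 at 0.72, Mki67 at -0.16 and Ccnd1 at -0.14. Interferon response genes had a median of 0.46, with Ifi27l2a 2.07-fold higher, and NRF2 targets 0.41, with Cbr3 at 0.80 and Akr1b8 at 0.71. Inflammatory genes had a median of 0.19, while matrix genes (-0.04) and p53 targets (-0.03) were near 0. Beside the interferon and inflammatory groups, macrophage markers had a median of 0.41, with Cd14 at 1.09 and Marco at 0.99. The cholangiocyte markers had a median of 0.36 (0.17 over all measured members), and gallbladder and intestinal epithelium markers 0.46.

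For this comparison 10 lists stood above the central 95% of random lists and 9 below it.

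The effects of the CA diet without and after DEN, which share no array, correlated across expressed genes at 0.41 (Pearson). Of 11651 genes, 28 were at least 2-fold lower in both and 9 at least 2-fold higher in both, where independent lists of these sizes would share 0.326 and 0.205, and none was 2-fold different in opposite directions. The genes lower in both included Cyp8b1, Cyp7a1, Asns, Moxd1 and the fatty acid omega-hydroxylase gene Cyp4a14, and those higher in both included Obp2a, Fos, Hsd17b6, Socs2, Ifi27l2a and Mmp12, a macrophage elastase.

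**Figure D3:**
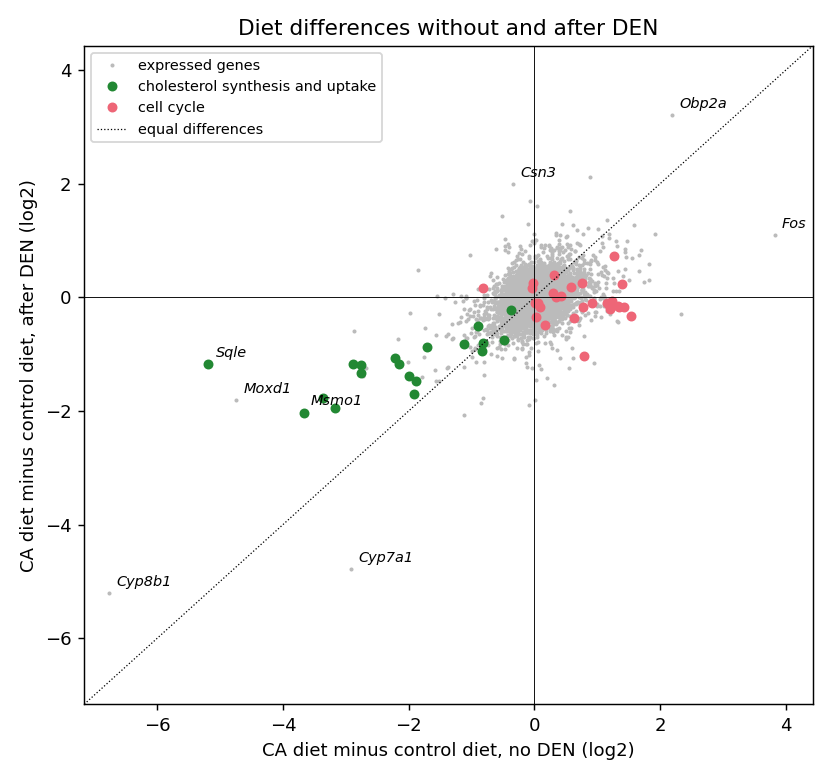
Log2 difference between the CA diet and the control diet without DEN (horizontal) and after DEN (vertical), 1 point per expressed gene, with genes of cholesterol synthesis and of the cell cycle coloured; the dotted line marks equal differences. Sqle lies at -5.19 and -1.18, Cyp7a1 at -2.91 and -4.78, and the Pearson correlation over all expressed genes was 0.41.

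The difference between these diet effects, after DEN minus without DEN, was at least 1 on the log2 scale for 51 genes and at most -1 for 85 (68 and 70 with each array centred on its median). It rests on all 4 arrays, 1 per group, and was not tested. Sqle had the highest value, 4.01, and Moxd1 stood at 2.94. Both were under 4.855 on the CA diet without DEN, and with low values raised to it they stood at 3.84 and 2.29. The cholesterol list had a median of 0.84, with Hmgcs1 at 1.70, Msmo1 at 1.64 and Fdps at 1.59, so that these genes were less low after DEN, although a further probe set of Hmgcs1 stood at -0.44. Cyp7a1 stood at -1.87 and Cyp8b1 at 1.55, although both were at background on the CA diet after DEN and Cyp8b1 also without DEN. With low values raised they stood at -1.81 and 1.25. For Cyp8b1 both CA diet levels are then equal. Its 1.25 therefore only restates its lower level in the DEN control diet pool and says nothing about the diet effect after DEN. The acute phase gene Orm2 (2.32), the casein gene Csn3 (2.34), Fmn1, a formin (2.27), and Wfdc12 (1.95) were also positive. With low values raised Fmn1 stood at 1.79, and with the mean over its probe sets at 1.06. Fos (-2.73), Cyp2b9 (-2.62), the lysolipid transporter gene Mfsd2a (-2.11), Ube2c (-1.86, or -1.33 with low values raised) and Tspan13 (-1.86) were also negative. The cell cycle list had a median of -0.60 (-0.39 with low values raised), with 12 of 28 at -1 or less, and the matrix list had a median of -0.28. The hybridization controls reached 0.572 in this double difference and the poly-A controls had a median of -0.67.

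DEN against no DEN on the CA diet gave a similar tumour profile. The oncofetal list had a median of 2.24, with 17 of 25 genes at least 2-fold higher. Afp was at least 159-fold higher, Tspan8 at least 119-fold, Cpe at least 90.8-fold, Scd2 43.7-fold, Csn3 at least 42.6-fold, Bex1 at least 26.9-fold, Lcn2 32.9-fold and Fst, the activin antagonist follistatin, at least 46.5-fold. The most strongly lower genes were Upp2, 16.7-fold, Cyp2b10 13.2-fold, Mfsd2a 11.0-fold, Thrsp 10.3-fold, Dbp 8.15-fold, Usp2 7.36-fold and Lpin1 7.15-fold. As lists, fatty acid synthesis (median -0.04) and lipid droplets (-0.11) were near 0. The endothelial lipase gene Lipg was at least 3.69-fold lower, with another probe set at 0.19, and the lowest probe sets of Afp and Cpe stood at 0.04 and -0.41. In all, 553 genes were at least 2-fold higher and 204 lower.

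Cell cycle genes had a median of 0.72 in this comparison, with 11 of 28 at least 2-fold higher, Mki67 at 1.67 and Ccne2 at -1.53. Cholesterol genes had a median of 1.01 with 10 of 19 at least 2-fold higher, led by Sqle (at least 18.5-fold), Cyp51 (3.58-fold) and Dhcr7 (3.41-fold). Clock genes had a median of -1.08, with Arntl at least 7.69-fold higher. Stress genes Asns and Trib3 were at least 7.13-fold and 6.54-fold higher, and the p53 targets Btg2 and Cdkn1a 7.21-fold and 4.42-fold. Bile acid synthesis had a median of -0.50 and the receptors and transporters -0.22, with Slco1a4 3.45-fold lower. Inflammatory, interferon and matrix lists had medians of 0.52, 0.85 and 0.56, beside medians of 0.51 for macrophage and 1.08 for dendritic cell and MHC class II markers (0.26 for the latter over all measured members). Stellate cell and fibroblast markers stood at 0.34 and endothelial markers at 0.32. Cholangiocyte markers stood at 1.476 and neutrophil markers at 1.75, but at 0.24 and -0.0733 over all measured members. The effects of DEN on the 2 diets, which share no array, correlated at 0.86 across expressed genes. They had 404 genes at least 2-fold higher in both (28.3 for independent lists), 82 lower in both (1.84) and none in opposite directions. For DEN on the CA diet 17 lists stood above the central 95% of random lists and 11 below it.

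Against the untreated control, the pool with both treatments had high tumour markers and low genes of bile acid synthesis. Tspan8 (at least 119-fold), Afp (at least 159-fold), Cpe (at least 90.8-fold), Gpc3 (at least 29.4-fold) and Prom1 (at least 30.6-fold) were higher, and Cyp8b1 (at least 88.2-fold), Cyp7a1 (at least 50.05-fold), Upp2 (16.7-fold) and Thrsp (10.1-fold) were lower. Mup10, a major urinary protein gene whose family is nearly identical in sequence, was 7.44-fold lower, and Slc8a1, a sodium-calcium exchanger gene, at least 3.80-fold lower on the probe set used (another at -0.02). Slc51b was 3.07-fold higher, Nr0b2 1.56-fold higher, Slc10a1 2.82-fold lower and Nr1h4 2.23-fold lower. Interferon genes had a median of 1.31 with 11 of 18 at least 2-fold higher, and inflammatory genes a median of 1.04 (0.65 over all measured members) with 11 of 22, led by Egr1 (4.20), Cxcl9 (3.23), Cxcl10 (2.67) and Cxcl1 (2.23). Macrophage markers had a median of 1.08 with 9 of 16 at least 2-fold higher, neutrophil markers 2.40 and cholangiocyte markers 1.85. Over all measured members the neutrophil median turned to -0.0417 and the cholangiocyte median was 0.46. Cell cycle genes had a median of 1.45 (1.01 with low values raised) and NRF2 targets 0.58, with Cbr3 at 4.75. Cholesterol genes had a median of -0.93. In all, 696 genes were at least 2-fold higher and 256 lower, or 593 and 347 with each array centred on its median. Here 17 lists stood above the central 95% of random lists and 10 below it.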

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

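The equal-addition test in this part was chosen after the results were seen, while the values with raised low levels, loess centring and unmatched lists were planned and used as tests only later. The cell cycle list stands out because its median was 0.70 for the CA diet without DEN and -0.11 for the CA diet after DEN, opposite signs. The latter lay at percentile 1.62 among matched random lists but at 2.93 among unmatched ones, which is inside the central 95%. The difference was not tested, since each group was 1 array. Levels near the array floor do not account for all of it, because with low values raised to 4.855 the list median of the difference between the diet effects was still -0.39 against -0.60, with an SD of random list medians of 0.0605. An intensity trend between arrays is argued against by loess centring, which left -0.55. If the diet had added the same amount of these transcripts to the higher level after DEN, the measured effect would have matched the expected one. It lay below it by a median of -0.38 (spread 0.344 over the 28 members), but by -0.21 (spread 0.401) with low values raised, so the genes near the floor keep this explanation open. Also open are a variation between pools and a diet effect on dividing cells that may differ after DEN, which 1 array per group leaves untested. The poly-A controls moved in the same directions, with medians of 0.31 for the diet without DEN and -0.35 after DEN. In the difference between the diet effects they had a median of -0.67, while all expressed genes had -0.04. Whether what moved these controls also moved the list was not tested.

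Probe sets without a single named gene were outside the comparisons. Of 3031 such expressed probe sets, 102 were at least 2-fold higher with DEN on the control diet (3.37%, against 5.12% of named genes) and 9 were at least 2-fold higher with the CA diet without DEN (0.297%, against 0.661%).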

How the results depend on the processing

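All alternatives were planned. Each group was 1 array, so leaving an array out would remove its group, and no fit across the 4 arrays was made. Of 116 alternative values of counts and agreement 80 stayed within 1.5 times the reported count or within the interval of the correlation, and 36 moved. That interval takes genes as independent replicates, which they are not, so it is too narrow. Of 4925 values of named genes 4641 moved by less than the spread over genes, 284 moved more and 0 turned sign among 2-fold genes. The mean over probe sets moved 182 of 985 and raised low levels 102 of 985, while quantile normalization, median centring and loess centring moved 0 of 985 each. Median centring shifts all genes of a comparison alike by less than that spread, so its outcome was fixed in advance and the total overstates stability. Of 1554 list medians 1237 stayed within the SD of random lists, 310 moved and 7 turned sign; of 222 list percentiles 207 kept their side. In the order CA diet without DEN, DEN on control diet, CA diet after DEN, DEN on CA diet, both treatments against none, and difference between diet effects, the 1.5-fold threshold gave 290, 1298, 156, 1205, 1407 and 262 higher and 206, 503, 206, 699, 797 and 371 lower genes, by its construction. It gave 50 and 78 genes shared by the diet effects and 909 and 352 shared by the DEN effects (higher and lower). The upper quartile filter, which tests fewer genes, gave 46, 309, 13, 285, 355 and 26 higher genes and 37 lower for the difference between diet effects. The mean over probe sets gave 397 higher genes for DEN on the control diet and 54 lower for the difference between diet effects. Counting every probe set gave 177, 90, 337 and 427 lower for the 4 comparisons from DEN on the control diet on, and 81 higher for the difference between diet effects, as did no filter (81). Centring on the median gave 192 lower for DEN on the control diet. It shifted the median of all genes by -0.16 there and by -0.12 for both treatments against none. Before it, the medians over expressed genes were 0.035 and 0.012, so it moved them away from 0. It made 70.3% instead of 85.0% of the 2-fold genes higher with DEN on the control diet. Loess centring gave 84% there and quantile normalization 81.3%. The diet effects correlated at 0.258 (Spearman) and 0.298 (all genes), the DEN effects at 0.747 and 0.805. The mean instead of the median turned the lipid droplet list to 0.13 for DEN on the control diet, and the periportal list to -0.000455 for the CA diet after DEN and 0.20 for DEN on the CA diet. All measured members turned the neutrophil list to -0.0867, -0.0733 and -0.0417 for DEN on the control diet, DEN on the CA diet and both treatments, and the erythroid list to 0.11 for the difference between diet effects. Beyond fewer or more genes tested, the cause was not tested. Levels under 4.855 are close to background and limit every fold that starts there.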

Other observations

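Sex-biased, zonal and several metabolic lists were not described above. All 4 pools expressed the Y-linked genes Eif2s3y (9.57, 9.60, 9.31 and 9.27), Kdm5d and Uty, and Xist lay at 3.87, 3.85, 3.51 and 3.60, under the expression limit. The sex chromosome list had a median of 0.03 for the CA diet without DEN and -0.04 for DEN on the control diet. With DEN on the control diet the male-biased list had a median of -0.81, with the steroid dehydrogenase Hsd3b5 at -1.21 and Susd4 at -1.35. The female-biased list had a median of 1.87 over 9 expressed members and 0.76 over all 17 measured ones, with the peroxisomal transporter gene Abcd2 at 3.41 (its lowest probe set at 0.17) and the steroid hydroxylase Cyp17a1 at 2.44, although Prom1 (5.21) is also a tumour marker of the lists. On the CA diet DEN gave -0.70 and 0.35 for these lists (0.22 for the latter over all measured members). WNT and pericentral genes had medians of -0.62 and -0.50 for DEN on the control and CA diets, with Cyp1a2 at -1.18 and -1.52 and the glutamate transporter gene Slc1a2 at -1.13 and -1.43, and Glul, glutamine synthetase, at -0.70 and -0.35. Periportal genes had medians of -0.21 and -0.33 but means of 0.33 and 0.20, with the apolipoprotein gene Apoa4 at 3.71 and 3.38.

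Phase I drug metabolism had a median of -0.44 (mean -0.05) for DEN on the control diet and 0.14 for the CA diet without DEN. Oxidative phosphorylation had medians of -0.22 for DEN on the control diet and -0.31 on the CA diet, fatty acid oxidation -0.24 and -0.32, and ribosomal proteins 0.20 and 0.23. With each array centred on its median, DEN on the control diet gave -0.38, -0.40 and 0.03 for these 3 lists, and ribosomal proteins stood at 0.14 on the CA diet. In the same comparisons, glucose and glycogen genes had medians of -0.19 and -0.38 (means 0.08 and -0.13), with the glucose transporter gene Slc2a2 at -0.98 and -1.20. Glutathione transferase Gstp1 was at 14.05, 14.16, 14.03 and 14.10 on the 4 arrays. Erythroid markers had medians of -0.77 for DEN on the control diet and -1.43 on the CA diet (-0.45 over all measured members), with the carbonic anhydrase gene Car1 at -1.07 and -1.67. Exocrine pancreas markers stood at -0.15 and 0.13, and of the adipocyte markers only Lipe (-0.44 for DEN on the control diet) and Retn (-0.41) were expressed.

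The tests in the remaining paragraphs were chosen after the results were seen, except that the cholesterol median with raised low levels was planned and used as a test only later. Clock genes differed between DEN and no DEN in opposite directions. A loss of hepatocytes in the DEN pools as large as the drop of the late clock genes is argued against. The hepatocyte list had medians of -0.12 and -0.25 (spreads 0.297 and 0.371). In contrast, 9 clock genes of the late phase, such as Dbp, Tef and Per3, had medians of -1.01 and -1.73. A smaller loss of hepatocytes is not excluded by these values. A different clock phase at collection is a candidate explanation, because 4 genes of the opposite phase, Arntl among them, stood above the late ones. This gap was 1.66 for DEN on the control diet and 2.42 on the CA diet. For the CA diet against the control diet without DEN it was -0.47, the other way, with a clock list median of 0.18. The spreads there were 0.892 over these 4 genes and 0.423 over the late ones. After DEN the gap between the diets was 0.16. Clock genes thus also differed somewhat between the pools without DEN. A clock altered by DEN or in tumours could also differ at the same collection time. These 2 explanations cannot be told apart with 1 collection per group. The Upp2 and Usp2 differences between DEN and no DEN may share this source.

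Cholesterol genes were less low on the CA diet after DEN than without DEN (median of the difference 0.84). Levels near the array floor are argued against, since with low values raised to 4.855 this median was still 0.84 (0.83536). Some cells may ignore the diet but express Cyp7a1 and Cyp8b1 as the others do. The Cyp7a1 left after DEN on the CA diet, with its low level raised to 4.855, allows at most 3.78% of such cells. The 14 cholesterol genes that were 2-fold lower without DEN would need a median share of 25.1% (spread 12.5, lowest 5.63). That share assumes that all other cells responded to the diet as without DEN, and only under this assumption are such cells argued against. Cyp7a1 itself fell further with the diet after DEN (-4.78) than without it (-2.91). The assumption does not allow this, so the needed share is uncertain. Cells that ignore the diet and lack these enzymes, such as tumour cells might, remain open, since Cyp8b1 in the DEN control diet pool was 42.0% of its level without DEN, which leaves room for that share.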
